A study of Homo sapiens with 24 samples.

How the data were processed

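The series measured transcripts with an Affymetrix array in HAP1 cells, a near-haploid human line, on 24 arrays. The 6 lines are the parental line (PAR), S51A (named for a change in the translation factor eIF2-alpha that removes the serine phosphorylated under stress) and lines named for the loss of the eIF2-alpha kinases HRI, GCN2, PKR and PERK. Cells had no drug, lomustine at 200 µM for 2 h, or the treatment titled SA100 for 2 h. The title of the SA100 arrays and their agent field conflict, since the latter names lomustine. The treatment text describes sodium arsenite at 100 µM, so these arrays were grouped by title and read as arsenite. The labels letter the repetitions of PAR, S51A and HRI as A and B for the untreated and lomustine arms and do not say whether they are separate cultures.

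The deposited table holds 53617 probe sets with values in log2 units, per the labels processed with RMA (background correction, quantile normalization of probes and a median-polish summary) and the R package affy. The submitters' processing notes give no versions, filters or genome build, so no coordinates are printed. Values ran from 0.71 to 12.47 on the log2 scale, and the medians of the arrays from 2.34 to 2.58. Arrays give no read depth, and the number of arrays limits the precision. No control probe sets for RNA quality were in the table (0 with the usual prefix), so the planned comparison of signal from both ends of control transcripts could not be made.

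Probe sets were joined to gene symbols with the array's annotation. Of the 25713 annotated probe sets, 23558 had exactly 1 symbol and were kept, which gave 22109 genes. The 2155 probe sets with several symbols were left out, as were the 27904 with none. For the 618 genes with more than 1 probe set, the one with the highest mean stood for the gene. A gene was tested if at least 2 of the 24 arrays reached the median of all values (2.42), which kept 17339 genes and left out 4770.

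Tests used R 4.3.3 with limma 3.58.1, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. A model with terms for arm and line over the 24 arrays (16 residual degrees of freedom) gave lomustine against no drug, SA100 against no drug and SA100 against lomustine. A model with 1 mean for each of the 18 groups of line and arm (6 residual degrees of freedom, from the 6 duplicated groups) gave the comparisons within and between lines. In it, the 12 groups of 1 array are assumed to vary like the duplicated ones. Letters were not used to pair arrays: the differences between A and B in the untreated and lomustine arms correlated over genes with r = 0.334 in PAR, -0.388 in S51A and -0.561 in HRI. Genes are not independent replicates, so these r carry no test. Some arrays were most alike across unlike letters. HRI without drug A was closest to HRI lomustine B (r = 0.982) and B to lomustine A (r = 0.984), against 0.968 between the untreated HRI arrays. S51A without drug B was closest to S51A lomustine A (r = 0.990), and PAR without drug B to PAR lomustine B (r = 0.987). The main fit within lines leaves any such pairing in its spread.

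The comparisons, tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule names EGR1, ATF4, EIF2S1 and the 4 eIF2-alpha kinase genes in every case. For each comparison across lines it takes up to 10 genes with the largest changes in each direction that passed the test and moved the same way in all 6 lines. For each comparison of duplicated groups it takes up to 5 in each direction whose arrays did not overlap. From each list it takes up to 4 members past the test, or the 2 with the smallest p.

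The 20 lists were integrated stress response, immediate-early genes, heat shock response, oxidative stress (NRF2 targets), metallothioneins and MTF1 targets, p53 targets, repair of alkylated and crosslinked DNA, unfolded protein response, NF-kB targets, interferon response, cholesterol synthesis, S phase, G2 and mitosis, stress granule components, apoptosis, cytosolic ribosomal proteins, mitochondrial transcripts, and markers of blood, epithelium and fibroblasts. The mitochondrial list had 0 members on the array, and 19 lists were tested. Through the matching of gene names, the ribosomal protein list as tested also held MRPL13, a mitochondrial ribosomal protein gene. Each was tested against the other genes with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment within each comparison. An estimated correlation between genes and fry, which tests whether a list moves on balance one way, were alternatives.

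Other alternatives were no filter and a stricter filter (14906 genes), the mean of all probe sets of a gene, quantile normalization of the table again, arrays centred on their medians, a trended robust prior, only the arrays compared, the mean of the line-wise contrasts, a replicate block, and leaving out each line or array in turn. Further ones were chosen after seeing the data, among them leaving out S51A lomustine B, and this array together with PAR lomustine A, which had the next-lowest median correlation to the others. The method was tested on simulated data with known changes. In the models across lines, changes of 1 log2 unit were recovered in 94.6% (lomustine), 98.4% (SA100) and 97% (SA100 against lomustine) of genes. Within PAR, recovery for lomustine was 3.1% for changes of 1 log2 unit and 59.3% for changes of 2 log2 units. Figures and table joins used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.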

Results

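Transcripts were measured on 24 arrays of HAP1 cells from 6 lines. Of these arrays, 9 came from cells with no drug, 9 from cells given lomustine (an alkylating and crosslinking drug used in chemotherapy) and 6 from cells given the treatment titled SA100, read as sodium arsenite. PAR, S51A and HRI had 2 arrays each without drug and with lomustine, and every other group of line and treatment had 1. One array, repetition B of S51A with lomustine, differed by more than 1 log2 unit from the median of the others in 8.72% of its probe sets. The next array, repetition A of PAR with lomustine, did so in 3.38%, close to HRI without drug A at 3.11%.

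**Figure D1:**
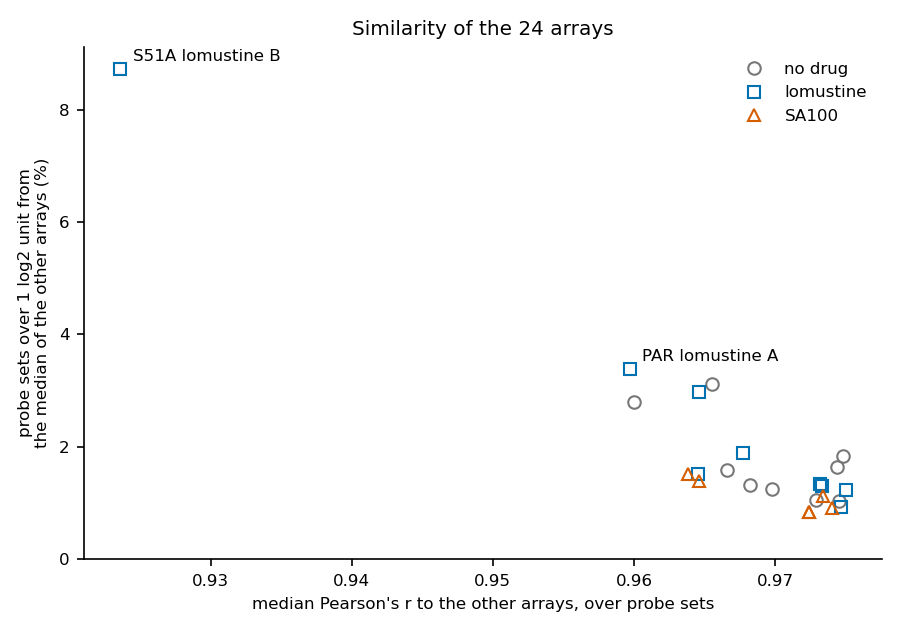
Each of the 24 arrays is plotted by its median correlation with the other arrays (horizontal axis, Pearson r over probe sets) and by the percent of its probe sets more than 1 log2 unit from the median of the others (vertical axis). S51A lomustine B lies apart at r = 0.924 and 8.72%. PAR lomustine A has the next-lowest correlation, r = 0.960, with 3.38%, close to other arrays; alternatives leave out both or the former alone.

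The first comparison asked which transcripts lomustine changed across the lines. EGR1 (probe set 16989736), an immediate-early transcription factor named in the title of the series, rose most: its mean was 4.17 without drug (SD 0.361, n = 9) and 7.75 with lomustine (SD 0.591, n = 9). This was a log2 change of 3.57 (SE 0.216, adjusted p = 2.5e-09), 11.9-fold, and EGR1 was higher in all 6 lines. JUN (probe set 16687875), part of the AP-1 transcription factor, rose by 2.11 (SE 0.28). So did CHAC1 (probe set 16799739), which degrades glutathione, by 1.67 (SE 0.287), and DDIT4 (probe set 16705961), an inhibitor of the growth kinase mTOR complex, by 1.77 (SE 0.273). ULBP1, a ligand for a receptor of natural killer cells, rose by 1.84 (SE 0.233), GADD45B, a stress-induced signalling gene, by 1.71 (SE 0.244), and SESN2, a nutrient-stress sensor, by 1.58 (SE 0.181). DUSP1, a phosphatase of MAP kinases, rose by 1.63 (SE 0.115), ZFAND2A, an arsenite-inducible partner of the proteasome, by 1.55 (SE 0.176), and FOSB, an AP-1 subunit, by 1.55 (SE 0.173).

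The transcripts that decreased most with lomustine included small nuclear and nucleolar RNAs, and each named here was lower in all 6 lines. SNORD75 had a log2 change of -2.28 (SE 0.224), SNORD12C of -1.95 (SE 0.327), SNORD72 of -1.49 (SE 0.33), SNORD4B of -1.49 (SE 0.282), SNORD35B of -1.30 (SE 0.217) and SNORA3B of -1.23 (SE 0.281). Such RNAs guide the modification of other RNAs. SNHG1, a host transcript of such RNAs, changed by -2.02 (SE 0.223). RNU12, a small RNA of the minor spliceosome, changed by -1.93 (SE 0.163), RPLP1, a ribosomal protein gene, by -1.57 (SE 0.148), and HMGN2, a nucleosome-binding protein gene, by -1.16 (SE 0.192). Means with lomustine lay below the median of all values (2.42) for SNORD72 (2.04) and HMGN2 (2.34); such values were not told from background, so these 2 changes are lower bounds in size. Probe sets for RPLP1, RNU12 and similar multi-copy genes may also detect related sequences.

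Across lines, limma called 43 genes higher and 135 lower with lomustine among 17339 tested. Of these, 21 of the former and 16 of the latter changed at least 2-fold. The balance of directions differed with arrays left out and with the scaling. Without S51A lomustine B, 61 genes were higher and 97 lower. Without both PAR lomustine A and S51A lomustine B, 81 genes were higher and 80 lower, and 101 were higher and 86 lower after the table was quantile normalized again. With fewer degrees of freedom, the mean of the line-wise contrasts gave 17 higher and 5 lower, and with fewer arrays the fit without PAR gave 25 and 25, all among the 178 calls. The count was 50 without the PAR line, 65 without GCN2, 94 without S51A, 93 without PERK, 102 without PKR and 109 without HRI.

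In the integrated stress response list (targets of the stress transcription factors ATF4 and CHOP), 7 of 32 genes rose with lomustine, 0 fell and 25 did not pass (8 and 0 adjusted over the list alone). Its largest changes were DDIT4, CHAC1, SESN2 and ATF3 (1.42, SE 0.208), itself a stress transcription factor. The list rose against other genes in camera (adjusted p = 3.3e-09, adjusted p = 0.11 with an estimated correlation). ATF4 itself had a change of 0.30 (SE 0.078, adjusted p = 0.065, higher in 6 of 6 lines), which did not pass. Immediate-early genes, which respond first to signals, had 8 of 36 members higher and 1 lower (11 and 4 adjusted over the list alone), led by EGR1, JUN, DUSP1 and FOSB. That list rose in camera (adjusted p = 4.3e-10, adjusted p = 0.051 with an estimated correlation). In the heat shock response, 5 of 18 genes rose (7 adjusted over the list alone): ZFAND2A, the chaperone genes DNAJB1 (1.29, SE 0.101) and HSPA1L (1.24, SE 0.168), and the co-chaperone BAG3 (1.11, SE 0.136) were its largest. Camera called it higher with the preset correlation (adjusted p = 3.2e-13) and with an estimated one (adjusted p = 0.048).

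The list of metallothioneins and other targets of the zinc sensor MTF1 fell with lomustine (median of 6 genes -0.46, adjusted p = 0.0014, adjusted p = 0.048 with an estimated correlation). SLC30A1, a zinc exporter, was its 1 gene past the test at -0.88 (SE 0.162; 2 genes lower adjusted over the list alone). Among 22 oxidative stress genes, HMOX1, a heme-degrading enzyme, was the 1 that rose, by 0.79 (SE 0.14; 1 adjusted over the list alone). The list's test gave no call (adjusted p = 0.62), and its median of -0.08 and mean of -0.01 were opposite in sign to the test. Of 26 p53 targets, 2 rose (PMAIP1, a promoter of apoptosis, by 0.72 with SE 0.133, and the kinase PLK2 by 0.47 with SE 0.112, a lower bound from a mean of 2.27 without drug) and 1 fell. The latter was MDM2, which marks p53 for degradation, at -0.70 (SE 0.149). Adjusted over the list alone, 2 were higher and 4 lower, and the list gave no call (adjusted p = 0.89), with a negative median and mean beside a positive test.

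Smaller changes appeared in 6 further lists that camera called with the preset correlation and not with an estimated one. Repair of alkylated and crosslinked DNA fell (median -0.18; adjusted p = 0.0088, adjusted p = 0.51 with an estimated correlation) with 0 of 21 genes past the test, 2 lower adjusted over the list alone. Its smallest p belonged to FANCF (-0.55, SE 0.134) and REV3L (-0.52, SE 0.146), which act in crosslink repair and in synthesis across lesions. The unfolded protein response fell (median -0.19; adjusted p = 0.0023, adjusted p = 0.42 with an estimated correlation), with SEL1L, of endoplasmic reticulum degradation, at -0.57 (SE 0.112) its 1 gene of 20 past the test (1 higher and 7 lower adjusted over the list alone). G2 and mitosis genes fell (median -0.18; adjusted p = 0.0014, adjusted p = 0.37 with an estimated correlation) with 0 of 18 past the test and 3 lower adjusted over the list alone; KIF23 (-0.30, SE 0.086) and KIF20A (-0.34, SE 0.098), motors of cell division, had the smallest p. Stress granule components fell (median -0.13; adjusted p = 0.0015, adjusted p = 0.37 with an estimated correlation), with the helicase DDX3X at -0.39 (SE 0.087) the 1 of 22 past the test (2 lower adjusted over the list alone). Cytosolic ribosomal proteins fell (median -0.11; adjusted p = 0.0011, adjusted p = 0.26 with an estimated correlation), with RPLP1 and RPL32 (-0.75, SE 0.164) lower among 19 (3 adjusted over the list alone). NF-kB targets rose (median 0.06; adjusted p = 0.030, adjusted p = 0.11 with an estimated correlation), with the regulator NFKBIZ at 1.16 (SE 0.163) the 1 of 15 past the test (1 adjusted over the list alone). After quantile normalization of the table none of these 6 passed, and the median of the ribosomal protein list was then 0.01. The 19 genes of that list as tested included MRPL13, of the mitochondrial ribosome.

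Apoptosis genes gave no call in camera (adjusted p = 0.16): PMAIP1 rose and XIAP, a caspase inhibitor, fell (-0.52, SE 0.121) among 21 (1 higher and 2 lower adjusted over the list alone). The interferon response had 1 of 12 genes lower, the exonuclease ISG20 at -0.35 (SE 0.085, a lower bound in size with a mean of 2.19 under lomustine; 1 lower adjusted over the list alone), and no call (adjusted p = 0.67), with median and mean below 0 and the test above. Cholesterol synthesis (14 genes, adjusted p = 0.35) and S phase (20 genes, adjusted p = 0.17) had 0 genes past limma's test and 0 adjusted over the list alone. Their smallest p belonged to LSS (-0.37, SE 0.129) and IDI1 (0.33, SE 0.136), enzymes of sterol synthesis, and to the replication genes RRM2 (-0.21, SE 0.068) and CCNE1 (-0.35, SE 0.136). Markers of blood (9 genes, adjusted p = 0.82), epithelium (10 genes, adjusted p = 0.092) and fibroblasts (7 genes, adjusted p = 0.081) likewise had 0 past the test and 0 adjusted over the list alone. The blood markers had a median and mean below 0 beside a positive test. CD14 (0.20, SE 0.108), HBE1 (-0.17, SE 0.115), KRT14 (0.21, SE 0.078), KRT19 (-0.25, SE 0.156), COL1A1 (0.17, SE 0.087) and TAGLN (0.20, SE 0.114) had their smallest p. The transcripts of the 4 kinases and of their substrate did not pass: EIF2AK1 (HRI) had -0.11 (SE 0.108), EIF2AK2 (PKR) -0.27 (SE 0.149), EIF2AK3 (PERK) -0.03 (SE 0.169), EIF2AK4 (GCN2) -0.06 (SE 0.101) and EIF2S1 (eIF2-alpha) -0.21 (SE 0.099).

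**Figure D2:**
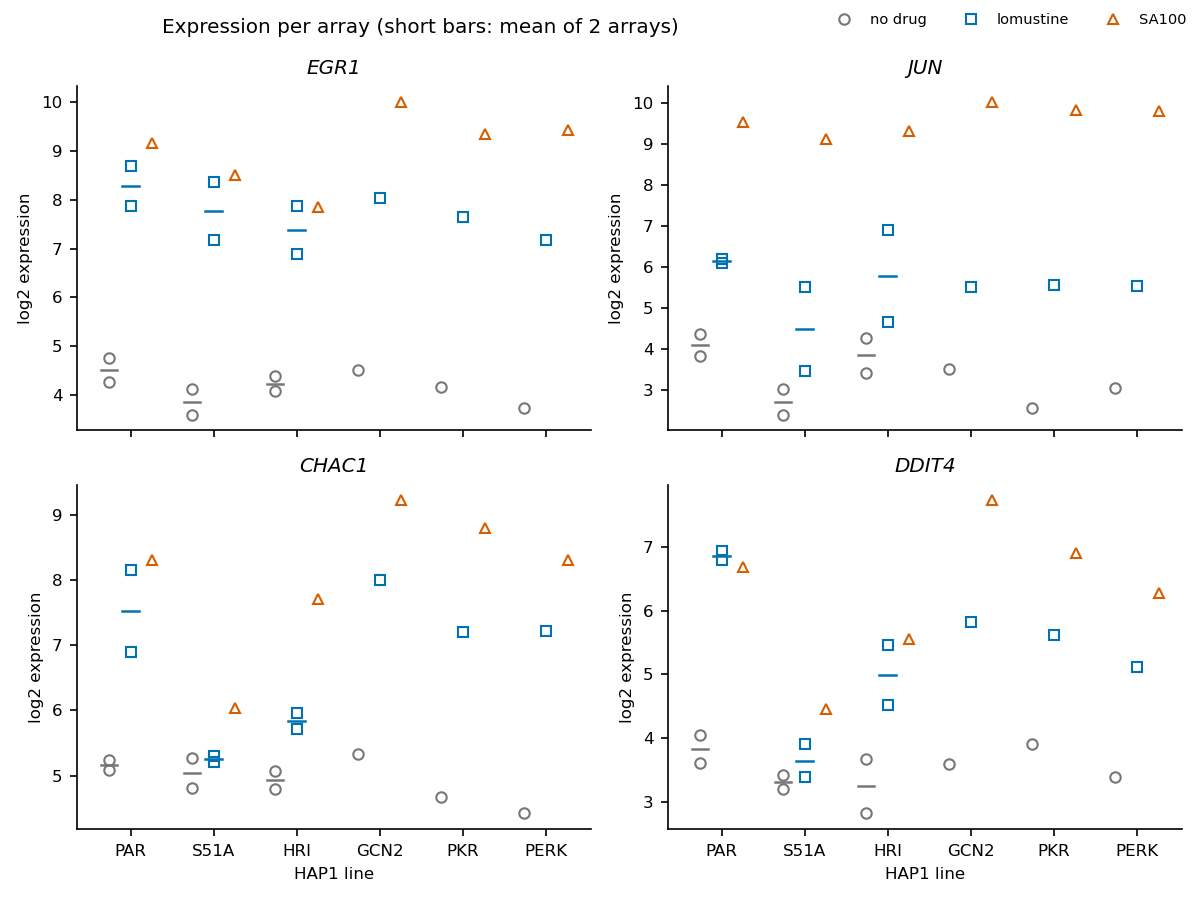
Log2 values of EGR1, JUN, CHAC1 and DDIT4 on each of the 24 arrays, by line and treatment; short bars are means of 2 arrays. EGR1 was between 6.89 and 8.69 on the lomustine arrays and between 3.59 and 4.75 on the untreated ones, while CHAC1 in S51A with lomustine was 5.21 and 5.30.

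The next comparison, SA100 against no drug, asked what the second treatment changed. JUN rose by 6.21 on the log2 scale (SE 0.316, adjusted p = 1.65e-11), 74.2-fold, and EGR1 by 4.85 (SE 0.244, adjusted p = 1.6e-11), 28.9-fold, to a mean of 9.06 (SD 0.760, n = 6). HMOX1 rose by 4.41 (SE 0.158), 21.2-fold, and DUSP1 by 3.94 (SE 0.13), 15.4-fold. FOS, the partner of JUN in AP-1, rose by 3.68 (SE 0.2), DUSP10, a phosphatase of stress-activated kinases, by 3.18 (SE 0.22), ZFAND2A by 3.03 (SE 0.199) and ATF3 by 2.71 (SE 0.234). CHAC1 had a change of 2.97 (SE 0.324), and MT1M, a metal-binding metallothionein, of 2.76 (SE 0.285); these 10 were higher in 6 of 6 lines.

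Small nucleolar and histone transcripts were among the largest decreases with SA100, lower in 6 of 6 lines. The changes were -2.69 for SNORD75 (SE 0.252; a lower bound in size, since its mean with SA100 was 2.24, below 2.42), -1.92 for SNHG1 (SE 0.251), -1.69 for RNU12 (SE 0.184), -1.56 for SNORD12C (SE 0.369), -1.50 for SNORD4B (SE 0.318), -1.31 for SNORD41 (SE 0.23) and -1.27 for SNORD35B (SE 0.245). The histone genes H3C13, H1-2 and H2BC26 changed by -1.89 (SE 0.258), -1.45 (SE 0.293) and -1.42 (SE 0.224). With SA100, limma called 365 genes higher and 165 lower, with 84 and 24 at least 2-fold. Centring the arrays turned the balance, to 292 higher and 485 lower, and quantile normalization gave 521 and 376. Without both PAR lomustine A and S51A lomustine B the counts were 724 and 485, without the latter alone 575 and 358, and the total was 262 without the array labelled PKR SA100. Leaving out a line gave 206 genes without PERK, 210 without GCN2, 213 without PKR, 336 without PAR and 345 without HRI. Without S51A there were more, 462 higher and 227 lower.

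Heat shock genes rose with SA100 in 17 of 18 cases (18 adjusted over the list alone; median 1.17), among them DNAJB1 (2.59, SE 0.114), BAG3 (2.35, SE 0.153) and DEDD2, a death-effector protein gene (2.19, SE 0.17). Immediate-early genes rose in 25 of 36 cases, with 0 lower (29 adjusted over the list alone; median 0.84). All 6 metallothionein and MTF1 genes rose (6 adjusted over the list alone; median 1.83), including MT1X (2.07, SE 0.182), MT1F (1.67, SE 0.27) and SLC30A1 (1.99, SE 0.183), which had fallen with lomustine. Camera called these 3 lists with the preset correlation (adjusted p = 2.9e-43, 8.8e-41 and 1.3e-16) and with an estimated one (adjusted p = 9.5e-05, 9.5e-05 and 1.3e-05). In the integrated stress response, 11 of 32 genes rose and 1 fell (11 and 4 adjusted over the list alone), with DDIT4 at 2.66 (SE 0.308) and SESN2 at 2.43 (SE 0.204); the list rose (adjusted p = 1.6e-06, adjusted p = 0.21 with an estimated correlation). ATF4 had 0.21 (SE 0.088, adjusted p = 0.22, higher in 5 of 6 lines). The transcripts of the kinases and of EIF2S1 ranged from -0.24 (EIF2AK2, SE 0.168) to -0.02 (EIF2S1, SE 0.112), and none passed.

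Of 22 oxidative stress genes, 3 rose with SA100 (5 adjusted over the list alone): HMOX1, the autophagy receptor SQSTM1 (0.65, SE 0.092) and the reductase TXNRD1 (0.34, SE 0.082). The list rose (adjusted p = 1.3e-04, adjusted p = 0.21 with an estimated correlation). Among p53 targets, 7 of 26 rose (8 adjusted over the list alone), with PMAIP1 at 1.36 (SE 0.149), the growth-arrest gene GADD45A at 1.18 (SE 0.152), the phosphatase PPM1D at 1.04 (SE 0.154) and PLK2 at 0.65 (SE 0.127, a lower bound as with lomustine). That list rose too (adjusted p = 5.3e-04, adjusted p = 0.21 with an estimated correlation). Apoptosis genes rose (4 of 21, 7 higher and 2 lower adjusted over the list alone; adjusted p = 0.0037, adjusted p = 0.21 with an estimated correlation), with MCL1, a survival gene, at 0.68 (SE 0.114) beside the death receptor TNFRSF10B at 0.49 (SE 0.111) and BBC3, a promoter of apoptosis, at 0.49 (SE 0.127).

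Camera placed 4 lists slightly lower with SA100. Repair of alkylated and crosslinked DNA had REV3L at -0.67 (SE 0.165) as its 1 call of 21 (1 adjusted over the list alone; adjusted p = 0.036, adjusted p = 0.68 with an estimated correlation). Cholesterol synthesis had LSS at -0.69 (SE 0.145) of 14 (1 adjusted over the list alone; adjusted p = 0.020, adjusted p = 0.68 with an estimated correlation). G2 and mitosis had CENPF, a kinetochore gene, at -0.76 (SE 0.177) of 18 (5 adjusted over the list alone; adjusted p = 0.022, adjusted p = 0.62 with an estimated correlation). Stress granule components had PABPC1, the poly(A)-binding protein gene, at -0.48 (SE 0.128) of 22 (1 adjusted over the list alone; adjusted p = 0.015, adjusted p = 0.62 with an estimated correlation).

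The remaining lists gave no call with SA100. The unfolded protein response had HERPUD1 (1.04, SE 0.216) higher, with a median of -0.03, a mean of 0.01 and a negative test (adjusted p = 0.39). NF-kB targets had the inhibitor gene NFKBIE (0.65, SE 0.158) higher (3 adjusted over the list alone), the interferon response had IRF7 (0.37, SE 0.088), and ribosomal proteins had RPLP1 lower (-1.13, SE 0.167). S phase genes and the 3 sets of markers of other cells had 0 genes past limma's test and 0 adjusted over the list alone. The fibroblast markers had a median and mean above 0 and a negative test (adjusted p = 0.58).

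**Figure D3:**
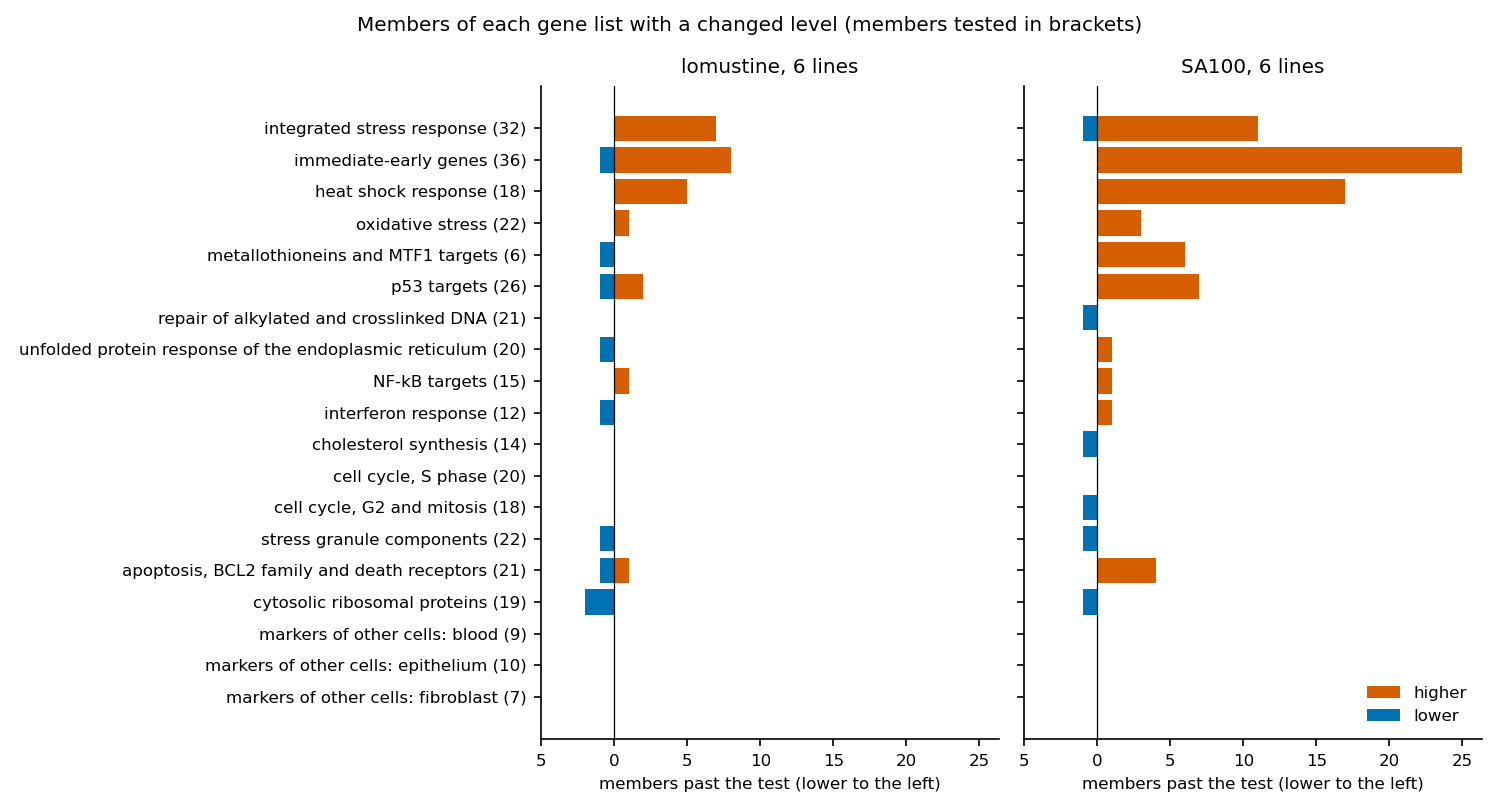
Bars give the number of members of each of the 19 tested lists that were higher or lower with lomustine (left) and with SA100 (right) past limma's adjusted threshold. With SA100, 25 immediate-early and 17 heat shock genes were higher, against 8 and 5 with lomustine.

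SA100 and lomustine were then compared directly, which asks how the responses differ. JUN was higher with SA100 by 4.11 (SE 0.316), HMOX1 by 3.62 (SE 0.158), MT1M by 3.33 (SE 0.285), SLC30A1 by 2.87 (SE 0.183), DUSP10 by 2.68 (SE 0.22), FOS by 2.53 (SE 0.2) and MT1X by 2.50 (SE 0.182). CCN1, a matrix signalling gene, was higher by 2.33 (SE 0.275), DUSP1 by 2.32 (SE 0.13) and RN5S85, a copy of the 5S ribosomal RNA gene, by 2.38 (SE 0.446). EGR1 was higher by 1.28 (SE 0.244, adjusted p = 0.0037). Of the stress genes induced by both, CHAC1 was higher with SA100 by 1.31 (SE 0.324), ATF3 by 1.29 (SE 0.234), the eIF2-alpha phosphatase subunit PPP1R15A by 1.01 (SE 0.144) and SESN2 by 0.85 (SE 0.204). DDIT4 (0.89, SE 0.308), ULBP1 (0.30, SE 0.263) and GADD45B (0.23, SE 0.275) did not pass.

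Lower with SA100 than with lomustine in 6 of 6 lines were SNORD41 (-1.66, SE 0.23), the uncharacterised LOC100287834 (-1.40, SE 0.341), the histone genes H2BC20P (-1.07, SE 0.272) and H2BC21 (-1.07, SE 0.26), MIR4279 (-1.03, SE 0.285), RN5S132 (-1.02, SE 0.258) and RN5S473 (-0.98, SE 0.235). So were HSD17B7, an enzyme of cholesterol synthesis (-0.99, SE 0.155), the synaptic adhesion gene NLGN2 (-0.85, SE 0.199) and ZC3H6 (-0.83, SE 0.232). HSD17B7 had risen with lomustine by 1.03 (SE 0.137). Means with SA100 lay below 2.42 for HSD17B7 (1.94, and 1.84 without drug) and MIR4279 (1.60), so their changes are lower bounds in size. For this contrast, limma called 950 genes higher with SA100 and 82 lower, with 90 and 6 at least 2-fold. The split narrowed to 643 and 328 after quantile normalization, 441 and 241 with centred arrays, 987 and 384 without both PAR lomustine A and S51A lomustine B, and 993 and 230 without the latter alone. The total was 471 without the array labelled PKR SA100, 328 without the PERK line, 439 without PKR, 452 without GCN2 and 657 without HRI.

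Metallothionein and MTF1 genes were higher with SA100 in 6 of 6 cases (6 adjusted over the list alone), MT1F by 2.16 (SE 0.27). So were 24 of 36 immediate-early genes (29 higher and 1 lower adjusted over the list alone) and 16 of 18 heat shock genes (18 adjusted over the list alone). Among the latter were the chaperone HSPA6 (1.87, SE 0.171, a lower bound since its mean with lomustine was 2.36), DEDD2 (1.73, SE 0.17), CHORDC1, a partner of HSP90 (1.56, SE 0.222), and ZFAND2A (1.48, SE 0.199). Camera called these 3 lists with the preset correlation (adjusted p = 3.5e-18, 3.0e-25 and 3.2e-25) and with an estimated one (adjusted p = 7.1e-06, 0.0015 and 0.0018). Oxidative stress genes were higher (3 of 22, 4 adjusted over the list alone, with SQSTM1 at 0.46 and TXNRD1 at 0.44; adjusted p = 1.5e-04, adjusted p = 0.22 with an estimated correlation). The p53 targets were higher (8 of 26, 13 higher and 1 lower adjusted over the list alone; adjusted p = 2.1e-04, adjusted p = 0.16 with an estimated correlation), with GADD45A at 0.90, the sugar-metabolism regulator TIGAR at 0.86, TNFRSF10B at 0.72 and PPM1D at 0.70. Apoptosis genes were higher (7 of 21, 10 adjusted over the list alone; adjusted p = 6.3e-05, adjusted p = 0.080 with an estimated correlation), with MCL1 at 0.80 and BAK1, a pore-forming promoter of apoptosis, at 0.65. The integrated stress response list had 6 of 32 genes higher and 2 lower (10 and 3 adjusted over the list alone) and no call (adjusted p = 0.24). The other 12 lists gave no call; the direction of the test differed from the median or the mean for NF-kB targets, S phase and the 3 sets of markers of other cells.

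The lines were next compared in their response to lomustine, since 5 of them are named for the loss of a kinase or for a change at the phosphorylated site. EGR1 had a change of 3.78 in PAR, 3.91 in S51A and 3.16 in HRI (SE 0.457, 2 arrays against 2), and of 3.53 in GCN2, 3.49 in PKR and 3.44 in PERK (SE 0.646, 1 against 1). CHAC1 had 2.38 in PAR, 0.22 in S51A and 0.90 in HRI (SE 0.359), and 2.67, 2.54 and 2.81 in GCN2, PKR and PERK (SE 0.507). DDIT4 had 3.04 in PAR, 0.33 in S51A and 1.75 in HRI (SE 0.369), and 2.24, 1.72 and 1.72 in the other three (SE 0.521). ULBP1 had 0.34 in S51A and from 2.02 to 2.38 in the other 5 lines. The 2 S51A lomustine arrays disagreed on ULBP1, with 7.02 on A and 5.53 on B against 6.01 and 5.86 without drug.

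As the test of the difference itself, the lomustine change in S51A minus that in PAR was -2.70 for DDIT4 (SE 0.521), -2.16 for CHAC1 (SE 0.507), -1.46 for ATF3 (SE 0.552) and 0.13 for EGR1 (SE 0.646). Over all genes limma called 0 (109 at an unadjusted p under 0.05). In the simulated data this comparison recovered 0% of differences of 1 log2 unit and 34.8% of 2 log2 units, so 0 calls do not show equal responses. Adjusted over the list alone, 2 of the 32 integrated stress response genes, DDIT4 and CHAC1, had a smaller change in S51A. As a list, 27 of the 32 had a smaller change in S51A than in PAR (median difference -0.34, adjusted p = 3.7e-13, adjusted p = 0.23 with an estimated correlation). Heat shock genes (median -0.21, adjusted p = 0.018, adjusted p = 0.90 with an estimated correlation) and G2 and mitosis genes (median -0.28, adjusted p = 0.0065, adjusted p = 0.90 with an estimated correlation) also had a smaller or more negative change, with 0 past limma's test in each. Neither of these 2 passed after quantile normalization (adjusted p = 0.22 and 0.48), nor without both S51A lomustine B and PAR lomustine A. Both arrays enter this comparison; without them the median difference of the integrated stress response was -0.23 (adjusted p = 9.9e-10, adjusted p = 0.38 with an estimated correlation). Leaving out PAR without drug B gave 2 genes in place of 0.

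HRI against PAR gave differences of -1.47 for CHAC1 (SE 0.507), -1.40 for ATF3 (SE 0.552), -1.28 for DDIT4 (SE 0.521) and -0.63 for EGR1 (SE 0.646). The same PAR arrays were subtracted for S51A, so the results of S51A and HRI are not independent of each other. The integrated stress response was lower (26 of 32 genes, median difference -0.26, adjusted p = 3.2e-08, adjusted p = 0.60 with an estimated correlation), as were immediate-early genes (median -0.12, adjusted p = 0.034, adjusted p = 0.97 with an estimated correlation). Other reference lines were chosen after the result was seen. Against GCN2, PKR and PERK, the integrated stress response had median differences of -0.143 in HRI, -0.264 in S51A and 0.084 in PAR. In the simulated data HRI against PAR recovered 0% of differences of 1 log2 unit and 20.6% of 2 log2 units. Over all genes limma called 0, with 155 at an unadjusted p under 0.05. For GCN2, PKR and PERK, with 1 array per arm, it also called 0, with 80, 92 and 126 at an unadjusted p under 0.05.

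**Figure D4:**
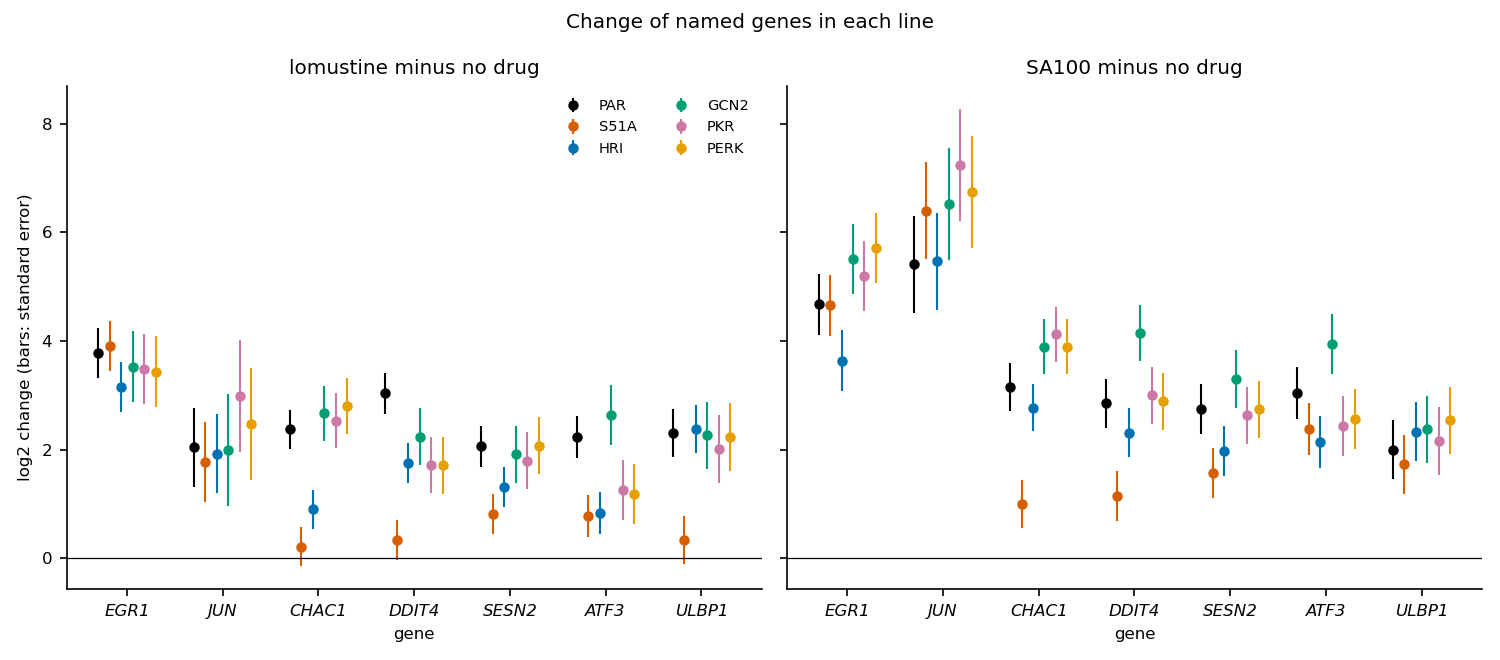
Log2 change (± SE) of EGR1, JUN, CHAC1, DDIT4, SESN2, ATF3 and ULBP1 in each of the 6 lines, with lomustine (left) and SA100 (right) against no drug. With lomustine, EGR1 lies between 3.16 and 3.91 in every line, and CHAC1 at 0.22 in S51A and 0.90 in HRI against 2.38 to 2.81 in the other lines.

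Within PAR, lomustine gave 0 genes past limma's test (503 at an unadjusted p under 0.05). EGR1 and DDIT4 shared the smallest adjusted p, 0.054. The stricter filter gave 2 genes, quantile normalization 3, centred arrays 2 and leaving out PAR without drug B 7, all lower, or PAR lomustine A 1. As lists, integrated stress response genes rose (7 adjusted over the list alone; median 0.26, adjusted p = 1.3e-17, adjusted p = 0.12 with an estimated correlation). Immediate-early genes (6 adjusted over the list alone) and heat shock genes (3) rose too (both adjusted p = 1.3e-09, adjusted p = 0.25 with an estimated correlation). DNA repair (adjusted p = 0.015, adjusted p = 0.70 with an estimated correlation) and stress granule genes (adjusted p = 0.044, adjusted p = 0.70 with an estimated correlation) fell. Neither of these 2 passed after quantile normalization (adjusted p = 0.10 and 0.17), nor without both PAR lomustine A and S51A lomustine B.

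S51A with lomustine had 2 genes past limma's test: EGR1 rose (adjusted p = 0.038) and RNU12 fell (-2.06, SE 0.228, adjusted p = 0.038). EGR1 lost its call with no filter and with a replicate block within lines or shared over lines. The block within lines gave 0 genes, and no filter and the shared block each gave 0 higher and 1 lower. A block with crossed letters, quantile normalization, centred arrays and the trended prior each gave 1 higher and 0 lower. RNU12 thus lost its call in those settings and with the block within lines. Without its repetition A, 1600 genes passed, which rests on repetition B alone, the array that stands apart. The count was 1 without repetition B and 0 without either untreated S51A array. Its integrated stress response list gave no call (0 adjusted over the list alone; median and mean of -0.04 beside a positive test, adjusted p = 0.38), and rose only after quantile normalization of the table (median 0.11, adjusted p = 0.024, adjusted p = 0.31 with an estimated correlation). Immediate-early genes rose (4 adjusted over the list alone; adjusted p = 9.4e-05, adjusted p = 0.42 with an estimated correlation), as did heat shock genes (1 adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.61 with an estimated correlation). G2 and mitosis genes fell (median -0.41, adjusted p = 2.8e-04, adjusted p = 0.42 with an estimated correlation), as did DNA repair (median -0.48, adjusted p = 0.0033, adjusted p = 0.61 with an estimated correlation). The unfolded protein response (adjusted p = 0.040, adjusted p = 0.69 with an estimated correlation) and stress granule genes (adjusted p = 0.028, adjusted p = 0.64 with an estimated correlation) were lower as lists, and NF-kB targets higher (adjusted p = 0.047, adjusted p = 0.34 with an estimated correlation). Markers of epithelium (adjusted p = 0.047) and fibroblasts (adjusted p = 0.039) were also higher as lists in S51A with lomustine (adjusted p = 0.34 with an estimated correlation for both). Without both PAR lomustine A and S51A lomustine B, 5 lists were called in S51A, 3 of them among these 9: immediate-early, heat shock, and G2 and mitosis genes. After quantile normalization 4 were called, 3 of them among the 9: immediate-early, heat shock and DNA repair genes.

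HRI with lomustine had 0 genes past limma's test (258 at an unadjusted p under 0.05). Heat shock genes rose as a list (4 adjusted over the list alone; median 0.29, adjusted p = 3.3e-12, adjusted p = 0.26 with an estimated correlation). So did immediate-early genes (3 adjusted over the list alone; adjusted p = 3.2e-04, adjusted p = 0.53 with an estimated correlation) and the integrated stress response (1 adjusted over the list alone; median 0.02, adjusted p = 0.0042, adjusted p = 0.53 with an estimated correlation). Metallothionein and MTF1 genes (median -0.48, adjusted p = 0.018, adjusted p = 0.26 with an estimated correlation) and ribosomal protein genes (adjusted p = 0.0090, adjusted p = 0.53 with an estimated correlation) fell. GCN2, PKR and PERK each had 0 genes past the test, with 138, 134 and 211 at an unadjusted p under 0.05.

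With SA100, HMOX1 had changes from 4.09 in S51A to 4.74 in PKR, and DUSP1 from 3.49 in HRI to 4.13 in GCN2. CHAC1 had 1.00 in S51A and from 2.78 to 4.13 in the other 5 lines. In single lines limma called 5 genes in PAR and the same number in S51A: EGR1, HMOX1, DUSP1, FOS and DNAJB1 in both, all higher. HRI had 4 (HMOX1, DUSP1 and DNAJB1 higher, H2AC20 lower), GCN2 and PKR 11 each and PERK 7. H2AC20 falls outside the rule for named genes and was chosen after its values were seen. Differences from PAR in the SA100 response were 0 genes in S51A, HRI, GCN2 and PERK (117, 441, 142 and 379 at an unadjusted p under 0.05) and 1 in PKR. The gene in PKR was TCEAL9 (5.47, SE 0.493, adjusted p = 0.0063), a transcription-elongation-like gene, also named after its values were seen. It read 2.00 in untreated PKR, below 2.42 and not told from background, so the size of 5.47 is uncertain. The value also rests on the array labelled PKR SA100, which is examined below.

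Lines were last compared without drug. In S51A, ZNF729 was higher than in PAR by 5.90 (SE 0.300, adjusted p = 1.3e-05; means 7.55 and 1.64, n = 2 each), ZNF257 by 5.09 (SE 0.322) and ZNF208 by 4.91 (SE 0.257); these encode zinc finger proteins. AMBN, an enamel protein gene, was higher by 5.46 (SE 0.92) and NLRP2, of the innate immune and germline NLR family, by 5.08 (SE 0.316). Lower in S51A were the membrane protein gene ITM2A (-5.18, SE 0.370), the receptor kinase EPHA3 (-3.29, SE 0.409), the kinase MAP2K6 (-2.90, SE 0.321), MIR1299 (-2.51, SE 0.319) and the lipid enzyme LPCAT2 (-2.28, SE 0.321). Means lay below the median of all values (2.42) in PAR for ZNF729, ZNF208 (2.09) and NLRP2 (1.92), and in S51A for EPHA3 (2.25), MAP2K6 (2.37) and LPCAT2 (2.39). Such values were not told from background, so these 6 differences are lower bounds in size. EGR1 had -0.64 (SE 0.457) and did not pass.

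In all, limma called 42 genes higher and 14 lower in untreated S51A than in PAR, and 96 in total when only those groups' arrays were used. The total was 28 without PAR A, 29 without PAR B, 32 without S51A A and 25 without S51A B. Metallothionein and MTF1 genes were lower as a list (median -0.40, adjusted p = 0.0042, adjusted p = 0.17 with an estimated correlation; 1 adjusted over the list alone). Untreated HRI had 0 genes past the test (311 at an unadjusted p under 0.05), and cholesterol synthesis genes were lower as a list (median -0.32, adjusted p = 0.036, adjusted p = 0.89 with an estimated correlation). Centring the arrays moved the median of all genes by 0.13 in this comparison, and without PAR without drug B it gave 3 genes. Untreated GCN2 had 1 gene, TCEAL9 (4.55, SE 0.323, adjusted p = 5.7e-04), and PKR and PERK 0 (354 and 422 at an unadjusted p under 0.05). Over the 6 untreated lines, mean log2 values of EIF2AK1 lay between 7.64 and 7.90, those of EIF2AK2 between 7.61 and 7.81, and those of EIF2AK4 between 5.84 and 6.28. EIF2AK3 lay between 3.33 and 4.64, and EIF2S1 between 6.20 and 6.64. For EIF2AK3, S51A read 3.79 and was not the lowest line. Its difference from PAR was -0.85 (SE 0.358), which did not pass. EIF2AK1 read 7.64 in HRI and 7.90 in PAR, a difference of -0.26 (SE 0.293), which did not pass. Probe sets may lie outside the edited part of a gene.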

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

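The estimated correlation, and the gene counts with centred arrays and after quantile normalization, were chosen beforehand. Their use to weigh explanations, the other tests of explanations, the list tests with combined settings and the other reference lines were chosen only after the result was seen.

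ULBP1, a ligand for a natural killer cell receptor, had a lomustine change of 0.34 in S51A against 2.02 to 2.38 in the other 5 lines, a gap of 0.821 of the whole range. On the S51A lomustine arrays it read 7.02 on A and 5.53 on B, and 6.01 and 5.86 without drug. S51A lomustine B had a median correlation over genes of 0.924 with the other lomustine arrays, which lay between 0.958 and 0.974. Of 63 groups examined for a lone extreme value, these 2 exceeded the limit, and chance gives about 1 in 20 groups.

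Several lists differed between lines in their response to lomustine by camera with the preset correlation, and on the values as deposited none did with an estimated one. The comparisons of S51A and of HRI with PAR subtract the same PAR arrays and are not independent. In S51A against PAR the median differences were -0.341 for the integrated stress response, -0.213 for heat shock genes and -0.283 for G2 and mitosis genes (adjusted p = 0.23, 0.90 and 0.90 with an estimated correlation). In HRI against PAR they were -0.262 for the integrated stress response and -0.115 for immediate-early genes (adjusted p = 0.60 and 0.97 with an estimated correlation). After quantile normalization the former had adjusted p = 0.027 with an estimated correlation, and 0.086 with centred arrays. The SA100 response of TCEAL9 in PKR exceeded that in PAR by 5.47. The size is uncertain, since TCEAL9 read 2.00 in untreated PKR, below the median of all values (2.42).

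The integrated stress response list responded less to lomustine in S51A than in PAR, with DDIT4, CHAC1 and ATF3 the clearest members. Leaving out both PAR lomustine A and S51A lomustine B leaves neither line with replicate lomustine arrays. The median difference was then -0.234, so a difference from PAR remained without these arrays, although unreplicated arrays cannot settle this. Against the mean of the other 5 lines it was -0.103 without them, with 17 of 32 members lower. With them it was -0.253, with 26 lower. These arrays may therefore hold much of the list-wide difference. The EGR1 change in S51A exceeded the mean of the other 5 lines by 0.435 (SE 0.525), so EGR1 gave no sign of a weaker exposure to lomustine. EGR1 is 1 gene and was not shown to follow the dose. Heat shock genes also changed less in S51A than in PAR (median difference -0.213), though not past the threshold with an estimated correlation. A weaker exposure therefore stays open. Chance spread of correlated genes fits the values as deposited. With an estimated correlation the list did not pass the 0.05 threshold with all arrays (adjusted p = 0.2315) or without the 2 arrays. The list passed after quantile normalization (adjusted p = 0.027) and with centred arrays (adjusted p = 0.026), so chance spread is not settled as the cause. A role of the S51A change itself is consistent with these values and remains an untested hypothesis, since clones of a line may also differ for other reasons.

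More genes were lower than higher with lomustine across lines (24.2% of 178 calls higher). Centring the arrays left 28.1% higher, which argues against a shift of whole arrays as the cause. Both other technical explanations fit: 50.3% of the calls were higher without both PAR lomustine A and S51A lomustine B. The share was 54.0% after quantile normalization, which removes differences in the shape of the distributions. Without S51A lomustine B alone, 38.6% were higher. The share also moved with both arrays kept. It was 43.1% without the GCN2 line, 27.5% to 32.3% without HRI, PKR or PERK, and 77.3% with the mean of line-wise contrasts. A higher share therefore does not single out these arrays. The excess of lower genes may come from a few arrays or from their distributions, but these shares cannot tell. No biological explanation for it was tested.

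The array labelled PKR SA100 lay away from its line on the genes that part PKR from GCN2 and from HRI, and TCEAL9 read 7.35 on it, 2.00 and 2.35 on the other PKR arrays, and 6.61 to 7.72 on those of GCN2. A GCN2 sample under a PKR label stays open, since over 29 genes the median position was 0.439 (0 for GCN2, 1 for PKR), with quartiles from -0.002 to 0.784. Between HRI (0) and PKR (1) it lay at 0.146 over 22 genes, nearer HRI than its own line, and between S51A (0) and PKR (1) at 0.892 over 99 genes, near its own line; a mixture of samples could give such positions but was not tested. SA100 itself moving these genes stays open too: the SA100 arrays of S51A and HRI stayed near their own lines (lower of the 2 median positions 0.961), while that of PERK lay at 0.298 from PAR, 0.426 from HRI and 0.612 from GCN2, and that of GCN2 at 0.559 from PAR. The genes were chosen on the same arrays that set 0 and 1, which were fewer for PKR, GCN2 and PERK than for the other lines. Differences chosen in this way tend to shrink on a further array, so low positions cannot settle the label. No biological explanation was tested.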

How the results depend on the processing

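Alternatives without the 2 arrays of lowest median correlation (PAR lomustine A and S51A lomustine B), S51A lomustine B alone or the PKR SA100 array, the crossed letters, the 12 lettered arrays alone, and list tests with combined settings were chosen only after the results were seen. EGR1 changed by 3.48 to 3.69 with lomustine under all alternatives run. No named gene with a call changed sign, and no list with a call was called in the opposite direction. The balance of higher and lower calls turned for SA100, with 365 and 165, and 292 and 485 with centred arrays. Lomustine had 43 and 135, and 17 and 5 with the mean of line-wise contrasts, where all 22 calls were among the 178. Where the value below differs, the cause was not tested, except that fewer arrays or degrees of freedom act in alternatives that leave arrays out, use only some arrays or average line-wise contrasts. Of 7946 values of named genes under alternatives, 7393 were the same by direction and side of the threshold, 385 lost their call, 54 gained one and 114 without a call changed sign. Of 1710 values of lists the numbers were 1310, 228, 25 and 147.

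For lomustine across lines (178 genes), only the 2 arms gave 114, the mean of line-wise contrasts 22, and leaving out a line 50 to 109. A replicate block shared over lines gave 9, the 12 lettered arrays without block 13, and the block with letters crossed in S51A and HRI 15. For SA100 (530), quantile normalization gave 897, line-wise means 136, leaving out a line 206 to 689, without the 2 arrays 1209, without S51A lomustine B alone 933, and without the PKR SA100 array 262. SA100 against lomustine (1032) gave 682 with centred arrays, 320 with 2 arms only, 104 with line-wise means, 328 to 906 without a line and 471 without the PKR SA100 array. Lomustine in PAR (0) gave 2 with the stricter filter, 3 with quantile normalization, 2 with centred arrays, 3 with the trended prior, 2 without the 2 arrays, and 0 to 7 without single arrays. In S51A (2) the count was 1 with no filter, 1 with quantile normalization, 1 with centred arrays, 1 with the trended prior, 0 with a replicate block within lines, 1 with it shared, 1 with it crossed, 0 with only the groups compared, 0 without the 2 arrays and 0 to 1600 without single arrays. The difference in lomustine response was 0 to 2 genes without single arrays for S51A and 0 to 2 for HRI. Untreated S51A (56) gave 96 with only those groups and 25 to 32 without single arrays, and untreated HRI 0 to 3. Comparisons with groups of 1 array (44 calls in all, where a gene called in several lines counts each time) gave 91 calls with quantile normalization. A replicate block shared over lines gave 45 genes for untreated S51A. A block within lines cannot be told from the line in untreated comparisons, and SA100 has no letters to block on.

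Numbers of lists called also moved, here given with the estimated correlation first. Lomustine across lines (10): 2, without the 2 arrays 3, quantile 4 with the preset and 4 with the estimated correlation, centred 3. SA100 (11): 3, fry 7, without the 2 arrays 3, quantile 6, centred 3. SA100 against lomustine (6): 3, and 3 without the 2 arrays. PAR (5): 0, fry 0, without the 2 arrays 1, quantile 3 with the preset and 3, centred 1. S51A (9): 0, fry 0, without the 2 arrays 5 with the preset and 1, quantile 4 with the preset and 0, centred 0. HRI (5): 0, fry 0, without the 2 arrays 0, quantile 1, centred 0. S51A against PAR response (3): 0, fry 0, without the 2 arrays 1 with the preset and 0, quantile 1 with the preset and 1, centred 1. HRI against PAR response (2): 0, fry 0, no filter 1, without the 2 arrays 0, quantile 1, centred 0. Untreated S51A (1): 0, fry 0, without the 2 arrays 2 with the preset and 0, quantile 2 with the preset and 0, centred 2 with the preset and 0. Untreated HRI (1): 0, fry 0, without the 2 arrays 2 with the preset and 0, quantile 0, centred 0.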

Other observations

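The tests of families in the first 2 paragraphs and the comparison of shared controls were chosen only after the results were seen. The splits of the arrays were planned.

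Beyond the fixed lists, some gene families held more of the called genes than their share of the genes tested. They were picked after these calls were seen, and Fisher's exact test treats genes as independent. The adjusted p given here therefore describe the excess and do not exclude chance. Small nucleolar and Cajal body RNAs were lower in 10 of 158 cases with lomustine (7 lower and 1 higher after quantile normalization, 8 lower with centred arrays; Fisher's exact adjusted p = 4.7e-06), while the family median was -0.02 (0.03 after quantile normalization). With SA100, 19 were lower and 4 higher (20 lower after quantile normalization, 24 with centred arrays; adjusted p = 2.2e-14). Histone genes, which package DNA, were lower in 3 of 33 cases with lomustine (2 and 3 under those scalings) and in 9 with SA100 (10 lower and 1 higher, and 12 lower; adjusted p = 3.5e-10). Ribosomal protein genes were lower in 8 of 53 cases with lomustine (6 under each scaling; adjusted p = 1.2e-07) and in 6 with SA100 (5 and 6; adjusted p = 9.8e-05). Of the KLF transcription factors, KLF2, KLF6, KLF7, KLF10 and KLF11 were higher with SA100 among 16 (5 under each scaling; adjusted p = 1.2e-04). Of 21 DUSP phosphatases, DUSP1, DUSP4, DUSP8, DUSP10 and DUSP16 were higher (6 after quantile normalization, 5 with centred arrays; adjusted p = 4.0e-04). Many of these genes are short, multi-copy or within host genes, so probe sets can pick up related transcripts.

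Zinc finger genes named ZNF made up 18 of the 42 genes higher in untreated S51A than in PAR, where 1.07 would be drawn from the 443 tested (18 after quantile normalization, 20 with centred arrays; Fisher's exact adjusted p = 2.0e-16). ZNF43, ZNF85, ZNF90, ZNF93, ZNF141 and ZNF208 were among them, and 0 were lower. Fisher's test treats genes as independent draws. Whether these genes lie together on a chromosome and changed as a block was not examined, so this adjusted p is descriptive. With SA100, 18 ZNF genes were higher and 0 lower (27 and 6 after quantile normalization, 18 and 5 with centred arrays; adjusted p = 0.041).

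In 100 splits of the arrays of the 2 arms within lines, the real one included, 1 gave as many genes as the real split in each comparison across lines. That 1 was the real split itself, so regrouping the arrays seldom gave such totals. The splits bear on the totals and not on each called gene. They cannot tell treatment from anything else tied to the arms. The real counts were 178 for lomustine (highest other 11), 530 for SA100 (highest other 406) and 1032 for SA100 against lomustine (highest other 453).

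Lomustine and SA100 share untreated arrays. Their changes correlated over genes with r = 0.433 and a covariance of 0.0235, and simulated data with no effect gave 0.444 and 0.00992. With no array in common r was 0.0312 for lomustine in PAR, S51A and HRI against SA100 in GCN2, PKR and PERK, and 0.298 for the reverse. Genes are not independent replicates. Genes called higher by both were 33, where independent lists give 0.905, and lower by both 31, where they give 1.29. The values for independent lists ignore the shared arrays.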
